A study of Homo sapiens with 5 samples.

How the data were processed

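The samples were 5 hybridisations of 1 RNA pool, per the labels total RNA of vastus lateralis muscle from insulin resistant people, on the 4 arrays of the Hu35K set and on HuFL. By the labels, then, the 5 values of a control probe set for a human transcript come from the same pool, and there was no second group and no repeated array. The spikes are control transcripts that are not part of the muscle RNA. Each deposited table gives 1 intensity per probe set on a linear scale, as whole numbers that can lie below 0, which the authors deposited without stating how they were scaled. The software, the background subtraction and any scaling between arrays are not given in the sources used here. From the values, the arrays were not brought to a common mean: after leaving out 2% of the probe sets at each end, the mean intensity was 196 on subA, 33.8 on subB, 58.1 on subC, 121 on subD and 200 on HuFL. Levels were therefore read within each array, and no value of 1 array was set against that of another except for probe sets with the same ID. All value columns were used.

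Probe sets were named through the platform annotation supplied with the series, brought to current symbols by gene identifier with the RefSeq gene table of assembly GRCh38.p14; no coordinates were used. Of 42553 probe sets that were not controls, 29711 had 1 gene symbol, 857 had several and 11985 had none. Of the probe sets with 1 symbol 29636 matched the RefSeq table. Only probe sets with 1 symbol named a gene, which gave 14729 genes; genes of the Y chromosome and XIST were left out. A letter before the final part of the probe set name (as in _s_at, _f_at or _i_at) marks shared or incomplete probe sequences, and 7169 probe sets (16.8%) carried one. Probe sets whose ID starts with AFFX, 58 on each array, were treated as controls; the Alu probe set was kept with the others and names no gene.

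The noise level of an array was the 95th percentile of the absolute values of its negative intensities, controls left out. It assumes that noise is about symmetric around 0. A gene was above noise when any of its probe sets lay above the noise level of its array. A gene's percentile was the median, over its probe sets, of the percentile rank of the probe set within its array, and genes at or above the 75th percentile were counted. Shares carry exact Clopper-Pearson 95% intervals, which count genes or probe sets as independent and cover counting only. Each list was placed among 10000 random lists of the same size, drawn from genes matched on array type and number of probe sets. Array type meant HuFL, Hu35K or both, without telling the Hu35K arrays apart. Above a low limit, genes were matched whatever their exact number of probe sets. The place among random lists describes this pool, and no p-value was computed because genes are not replicates. The correlation between array types has a percentile bootstrap interval from 500 draws of genes. A value that stood apart among the 5 arrays was found by the gap to its neighbour over the whole range, against a critical ratio of 0.71.

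There were 25 lists: genes of fast fibres, slow fibres and the common sarcomere; oxidative phosphorylation; the tricarboxylic acid cycle; glycolysis and glycogen; fatty acid uptake and oxidation; insulin signalling and glucose uptake; ribosomal proteins; proteasome subunits; markers of adipocytes, endothelium, blood, leukocytes, fibroblasts and matrix, smooth muscle, Schwann cells and nerve, and satellite cells; markers of heart, liver, brain and pancreas; stress response; cytokines; and mitochondrially encoded genes, of which none was measured. They held 694 genes, 594 of them measured and 30 of those listed only at 0. GYS1, HK2 and PPP1R3A stand in both the glycolysis and the insulin list and LIPE in both the fatty acid and the adipocyte list. Genes were named by rule: for each list the highest 2 and the lowest 1 by percentile, every measured gene of a core insulin list of 17, the brightest 3 named probe sets of each array, and control probe sets by ID. The lists, the naming rule, the noise level, the shares, the random lists and most alternatives were set before the data were examined. The noise level at the 75th percentile, the omission of subB, of subC or of HuFL values at 0, and the scaling by CreX were added after the data were seen. The main alternatives were another noise level, another rule for genes with several probe sets, omission of suffixed probe sets or of an array, and scaling of the controls by a trimmed mean or the 75th percentile.

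Part of the procedure, the place of a list's median percentile among 1000 random lists, was tested on simulated data with the 14729 genes. Of 480 lists tested over 20 permutations of the values, 18 (3.75%) fell outside the central 95% of random lists. All 4 lists planted with high values were recovered. A high place of either the median percentile or the share of genes at or above the 75th percentile counted as recovery. The planted values were high by construction, so recovery of weaker shifts was not tested. The share above noise was not tested in this way. The noise estimate was 0.970 of the simulated value. Because the simulated noise was symmetric around 0, this does not test that assumption on the arrays. Values on HuFL ran from -34247 to 26898. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 11.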

Results

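The material was total RNA from biopsies of the vastus lateralis, the large outer muscle of the thigh, combined into 1 pool from people described as insulin resistant. The pool was hybridised once to each of 5 oligonucleotide array designs, the 4 arrays of the Hu35K set (subA, subB, subC and subD) and the HuFL array. How many people contributed to the pool is not given in the sources used here, and no insulin sensitive pool was analysed here. The measurements therefore address which transcripts stood above array noise in muscle of this metabolic state, and they allow no comparison between groups. No array was repeated, so single values carry no error, and the number of arrays limits the precision. Each array held between 7071 and 8876 probe sets besides its 58 control probe sets, 42553 in all, and these represented 14729 named genes.

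The brightest named probe sets on the arrays belonged mostly to muscle fibre proteins, small heat shock proteins and the ribosome. On HuFL they were those of ATP2A1, the calcium pump of fast fibres (26898), MYBPC2, the fast form of myosin-binding protein C (22416), and TPT1, a translation-associated protein (19913). On subA they were RPS27, a ribosomal protein (13334), PPP2R3A, a regulatory subunit of protein phosphatase 2A (12289), and TMOD4, which caps thin filaments in skeletal muscle (12102). On subB they were MYOZ1, a Z-disc protein of fast fibres (5094), HSPB7, a small heat shock protein of heart and muscle (3903), and PPP1R3C, which targets protein phosphatase 1 to glycogen (3000). On subC they were CMYA5, a large muscle-specific protein (27613), GAPDH of glycolysis (24333) and RPS15 of the ribosome (18152). On subD they were the small heat shock proteins HSPB1 (16498) and HSPB6 (14155) and TXNIP, a thioredoxin-binding protein that restrains glucose uptake (13793). For PPP2R3A, CMYA5, MYOZ1, MYBPC2 and TXNIP, each with more than 1 probe set, every probe set on the arrays stood above noise, whereas RPS27 and RPS15 were listed at 0 on HuFL and other subD probe sets read -60 for HSPB1 and -448 for HSPB6. TPT1 on subB (-187), RPS15 on subC (-269), and HSPB7 (428) and GAPDH (455) on subD likewise had a probe set that was not above noise.

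Against the noise level of its own array, 7.58% of probe sets were brighter on subA (exact Clopper-Pearson 95% interval 7.04 to 8.15), 5.04% on subB (4.60 to 5.52), 5.46% on subC (4.99 to 5.95), 7.98% on subD (7.43 to 8.57) and 6.92% on HuFL (6.33 to 7.53). Counted by gene, 1909 of the 14729 named genes (13.0%) had at least 1 probe set above noise. The noise level, in intensity units, was 977 on subA, 299 on subB, 523 on subC, 667 on subD and 1230 on HuFL. Between 28.5% and 39.3% of values on an array lay below 0. If noise is symmetric around 0, it exceeds the level as often as negative values lie beyond their 95th percentile. Part of the probe sets above noise are then noise by construction: subB had 447 above noise and 3402 values below 0. A gene above noise through 1 probe set near the level may therefore be noise. The share above noise followed the threshold. With the noise level at the 99th percentile of the negative values in place of the 95th it ranged from 1.36% on subC to 3.18% on HuFL, and with any value above 0 counted it ranged from 55.2% on HuFL to 71.3% on subA.

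Most measured genes of the contractile apparatus were detected. Of the genes specific to fast fibres, 13 of 14 measured stood above noise (92.9%, 95% interval 66.1 to 99.8), led by ATP2A1 at the 99.99th percentile of its array and by MYH2, the type IIA myosin heavy chain, at 19460. PVALB, the calcium buffer parvalbumin, was the one not above noise, at 253. Among slow fibre genes 9 of 11 stood above noise (81.8%, 48.2 to 97.7), with TNNT1, slow troponin T, at 18426 on HuFL and 6876 on subC and TNNC1, the troponin C of slow fibres and heart, at 15057. The sarcomere genes common to both fibre types reached 21 of 29 (72.4%, 52.8 to 87.3), with TMOD4 at 12102 and TCAP, the titin cap, at 10800.

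Random lists of the same size, matched on array type and coarsely on number of probe sets, held on average 10.5%, 10.9% and 12.8% of genes above noise for the fast, slow and common lists. Each list's share lay at the 100th percentile of the 10000 random lists. The median gene percentile was 99.8 for fast fibre, 96.1 for slow fibre and 95.4 for common sarcomere genes. MYL2, the slow myosin light chain, MYBPC1, slow myosin-binding protein C, and ACTA1, skeletal actin, were listed only at 0 on HuFL and were counted as not above noise; ACTA1 was chosen for mention after its value was seen. On HuFL alone, 45% of the common sarcomere genes stood above noise.

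**Figure D1:**
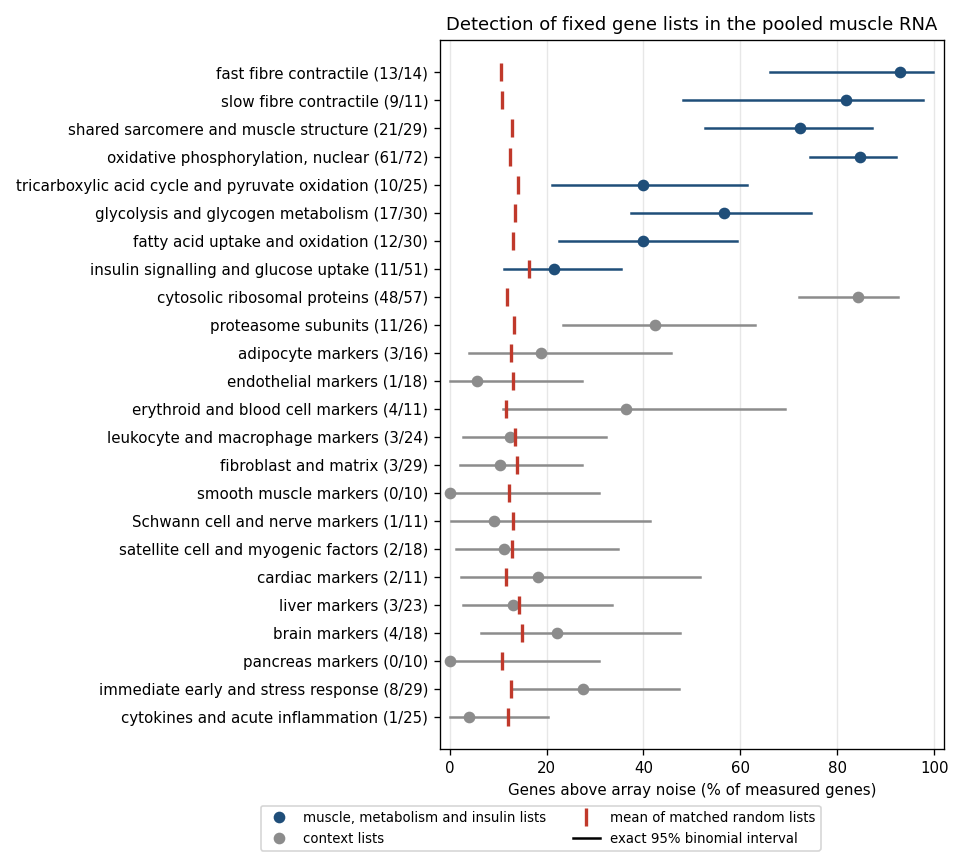
Share of the measured genes of each list that had a probe set above array noise, in percent, with exact 95% binomial intervals (lines), against the mean share of matched random lists (red marks). Counts of genes above noise and measured are given in brackets; fast fibre (92.9%), oxidative phosphorylation (84.7%) and ribosomal (84.2%) genes lie farthest to the right, and insulin signalling genes (21.6%) lie near their random mean (16.3%).

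Nuclear genes of oxidative phosphorylation were detected almost throughout. Of 72 measured genes, 61 stood above noise (84.7%, 95% interval 74.3 to 92.1; random mean 12.5%), and 57 lay at or above the 75th percentile of their arrays. UQCRQ, a small subunit of complex III, read 9357 on subA, and COX7A1, the muscle form of a cytochrome c oxidase subunit, read 16643 on HuFL. By complex, 26 of 32 genes of complex I, 1 of 3 of complex II, 6 of 8 of complex III with cytochrome c, 13 of 13 of complex IV and 15 of 16 of complex V stood above noise. ATP5PB, a peripheral stalk subunit of complex V, was the lowest of the list, at -300 and 0 on its HuFL probe sets. The list's share lay at the 100th percentile of matched random lists under every alternative tried, with shares from 68.1% to 94.4%. No gene of the mitochondrial genome had a probe set with a single gene symbol, so that list gave no value.

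Genes of glucose, glycogen and fat metabolism were detected well above the level of random genes. In the glycolysis and glycogen list 17 of 30 genes stood above noise (56.7%, 95% interval 37.4 to 74.5; random mean 13.5%), with PPP1R3C at 3000 on subB and GAPDH above noise with 3 of its 4 probe sets. PFKP, the platelet form of phosphofructokinase, was the lowest of this list, at -266 on HuFL, -82 on subB and 225 on subD. In the list of the tricarboxylic acid cycle and pyruvate oxidation 10 of 25 genes stood above noise (40%, 21.1 to 61.3; random mean 14.1%). Its highest members were the aspartate aminotransferases of the malate-aspartate shuttle, GOT2 at 4955 and GOT1 at 2528, and its lowest was PC, pyruvate carboxylase, with all 4 probe sets below 0. The list of fatty acid uptake and oxidation also had 40% above noise, 12 of 30 genes (22.7 to 59.4; random mean 13.2%). FABP3, the fatty acid carrier of heart and muscle, read 5162, and ACSL1, which activates long-chain fatty acids, stood above noise with 2 of 3 probe sets, whereas HSD17B10, a mitochondrial dehydrogenase, read -1462.

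The intervals of the 3 lists overlap, and the difference between them was not tested. Median gene percentiles were 85.9 for glycolysis and glycogen, 77.6 for the tricarboxylic acid cycle and 71.4 for fatty acids, at or above the 99.9th percentile of matched random lists. Without probe sets whose suffix marks shared or incomplete sequences, the glycolysis share was 34.6% and the fatty acid share 15.4%, the latter at the 86.3rd percentile of random lists; on HuFL alone the glycolysis share was 35.7%. The share of the tricarboxylic acid cycle was 16% with the 99th percentile and 64% with the 75th percentile as noise level.

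Genes of insulin signalling and glucose uptake were detected little more often than random genes. Of 51 measured, 11 were above noise (21.6%, 95% interval 11.3 to 35.3), against a mean of 16.3% in matched random lists, which placed the share at the 84.3rd percentile of those lists. The match did not tell apart genes with many probe sets, such as INSR and AKT1, so this random mean may be too low. The median gene percentile was 58.4, at the 95.2nd percentile of random lists. GYS1, muscle glycogen synthase, was the highest, at 2812 on HuFL, followed by TBC1D4, the Akt substrate that holds back glucose transporter vesicles, at 1181 on subA. CAPN10, a calpain, was the lowest, at -357 on subB.

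Among 17 core genes of the pathway 16 were measured and 6 stood above noise. SLC2A4, the insulin-responsive glucose transporter GLUT4, read 2377 on HuFL with 1 of its 3 probe sets, and the probe set of the same ID read 676 on subA, under that array's noise level of 977. AKT2, the kinase that carries the insulin signal to glucose transport, was above noise with 1 of 4 probe sets (1803 on subC). IRS2, an insulin receptor substrate, was above noise with 1 of 2 (755 on subC), and PTPN1, the phosphatase that acts on the insulin receptor, with 1 of 4 (433 on subB). The receptor itself, INSR, had none of 7 probe sets above noise, nor had IRS1 with 6 or AKT1 with 7. One AKT1 probe set fell just short, at 513 on subC against a noise level of 523, and most AKT1 probe sets carry a suffix that marks shared sequences. GSK3B and PRKAA2 with 4 each, PIK3R1, HK2 and GRB14 with 3 each, and GSK3A and PPP1R3A with 2 each were likewise not above noise. For INSR, IRS1 and PPP1R3A 1 of these probe sets each was listed at 0 on HuFL, which may be a missing value, so that PPP1R3A rests on 1 probe set, at percentile 90.1 of subB. Their percentiles ran from 14.5 for HK2 to 84.2 for AKT1; they were not detectable at this noise level, which does not show that they were absent.

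The insulin list's call depended on single probe sets. It was 5.88% where as many of a gene's probe sets had to lie above noise as not, 4.88% on HuFL alone, 3.92% with the 99th percentile as noise level and 52.9% with the 75th, and the share at or above the 75th percentile was 25.5% by the median and 58.8% by the highest probe set of each gene. Over the alternatives its place among random lists ran from percentile 30.3 to 85.6 for the share above noise and from 57.2 to 96.9 for the share at or above the 75th percentile.

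**Figure D2:**
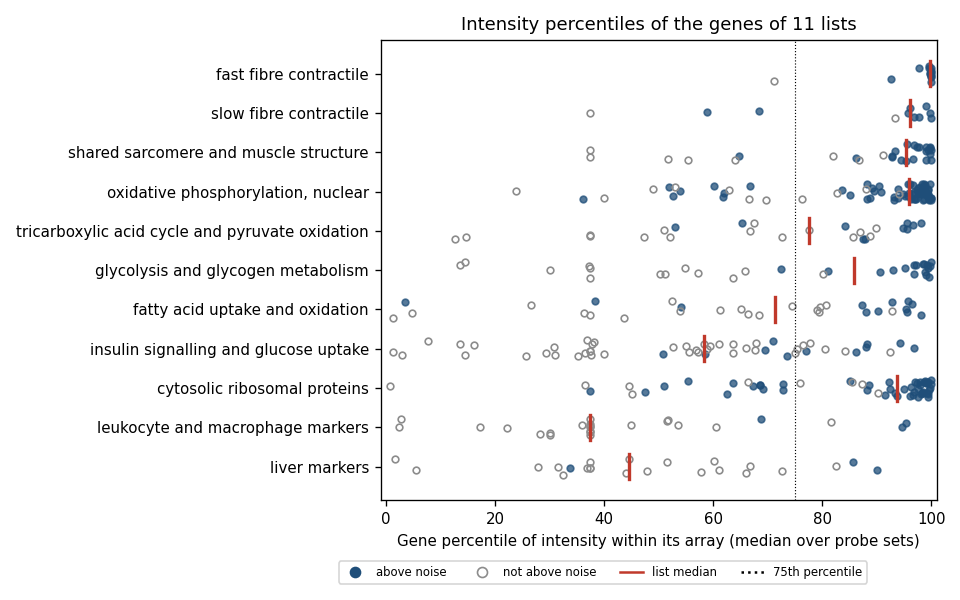
Percentile of each measured gene within its array (horizontal axis, median over the gene's probe sets, 0 to 100) for 11 lists; filled points are genes with a probe set above noise, open points are not, red bars are list medians and the dotted line is the 75th percentile. Among the muscle, metabolism and insulin lists, medians ran from 99.8 for fast fibre genes to 58.4 for insulin signalling genes. The ribosomal median was 93.7 and the liver median 44.5. The leukocyte median of 37.3 is the percentile given to every HuFL value listed at 0, and 4 of the 24 leukocyte markers were listed only at 0.

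Genes of protein turnover were detected unevenly. Of the cytosolic ribosomal proteins 48 of 57 stood above noise (84.2%, 95% interval 72.1 to 92.5; random mean 11.9%), with RPL30 at 11892 on subD and RPL4 at 7571 on subC. FAU, which encodes a ribosomal protein fused to a ubiquitin-like domain, was the lowest, at -1042. Of the proteasome subunits 11 of 26 stood above noise (42.3%, 23.4 to 63.1; random mean 13.3%), with PSMB6 at 3694 and PSMC3 at 2498 on HuFL. PSMB7 was the lowest of these, with none of its 3 probe sets above noise. On the Hu35K arrays alone the ribosomal share was 43.2%, still at percentile 100 of random lists, but the proteasome share was 20% (random mean 13.8%), at percentile 75.8. The proteasome share at or above the 75th percentile moved from 53.8% to 13.3% on these arrays, below the random mean of 20.3%. With the 99th percentile as noise level the proteasome share was 11.5%.

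At this noise level, markers of cells other than fibres were seldom above noise, and those of blood gave the highest share. The difference between these lists was not tested. With the 75th percentile as noise level, 62.5% of adipocyte markers stood above noise against 36.4% of blood markers. Of the erythroid and blood cell markers 4 of 11 stood above noise (36.4%, 95% interval 10.9 to 69.2; random mean 11.7%), the share lying at the 98.4th percentile of random lists. HBA2, an alpha-globin, read 17992 on subC with a probe set shared within its family, and ALAS2, the erythroid enzyme of haem synthesis, was above noise with 2 of 4 probe sets, whereas GP9 of platelets had none. The list's median percentile lay at percentile 51.7 of random lists, and without suffixed probe sets, which leaves out that of HBA2, the share was 11.1%, at percentile 61.8. The share was 80% on the Hu35K arrays alone and 11.1% on HuFL alone, where the beta-globin HBB and the delta-globin HBD, chosen for mention after their values were seen, were listed at 0. Of the leukocyte and macrophage markers 3 of 24 stood above noise (12.5%, 2.66 to 32.4), among them CD3E of T cells at 1826 and LYZ, lysozyme, with 4 of 5 probe sets; CD4 was the lowest, at percentile 2.44. Without suffixed probe sets none of the leukocyte markers stood above noise.

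Adipocyte markers had 3 of 16 genes above noise (18.8%, 4.05 to 45.6), while 7 of the 16 lay at or above the 75th percentile of their arrays, at percentile 99.1 of random lists. No adipocyte marker had as many probe sets above noise as not. PLIN1, the coat protein of fat droplets, read 484 on subD and was not above noise, AGPAT2 of triglyceride synthesis read 1604 on subC, and LIPE, hormone-sensitive lipase, was above noise with 1 of 3 probe sets. Of the fibroblast and matrix genes 3 of 29 stood above noise (10.3%, 2.19 to 27.4; percentile 31.3 of random lists) and 11 lay at or above the 75th percentile, at percentile 99.4 of random lists. On the Hu35K arrays alone these places for the share at or above the 75th percentile moved to 76.5 for adipocyte markers and 85.7 for fibroblast and matrix genes. TIMP2, a protease inhibitor, was above noise with 2 of 3 probe sets and SPARC, a matrix glycoprotein, with 1 of 4 (1460 on subD), whereas COL5A1 lay at percentile 15.1. Of the endothelial markers 1 of 18 was above noise, VWF at 703 on subD, while its other probe set read 152 on HuFL and was not. RAMP2 read 339 on subD and KDR, the VEGF receptor, -749 on HuFL. None of 10 smooth muscle markers was above noise (95% interval 0 to 30.8), including MYH11 at 607 on HuFL and 559 on subD, LMOD1 at 590 and TAGLN at -142.

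Of the Schwann cell and nerve markers 1 of 11 was above noise, SOX10 at 528 against a noise level of 523 on subC, and NEFH and PRPH were not; without subC the count was 0. Satellite cell and myogenic factors had 2 of 18 above noise (11.1%, 1.38 to 34.7). These were the transcription factors MEF2C, at 5764 on subD, and MEF2D, at 1674 on subA and 1278 on subB. Their other probe sets were not above noise. They read 295 on subC and 0 and 1076 on HuFL for MEF2C, and -2 on subC and 332 on subD for MEF2D. NCAM1 was not above noise with any probe set. Of the 18, 6 were listed only at 0, among them the myogenic factors MYOD1, MYOG and MYF6, chosen for mention after their values were seen; without HuFL values at 0 the share was 2 of 12 (16.7%).

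Lists for other organs gave the level that unrelated genes reached. Of the cardiac markers 2 of 11 were above noise (18.2%, 2.28 to 51.8), ACTC1, cardiac actin, at 4594 among them, while NKX2-5 at 1138 and MYL7 at -1114 were not. Of the liver markers 3 of 23 were above noise (13.0%, 2.78 to 33.6), including APOC3 at 1721 on subD and F2, prothrombin, at 632 on subB. Their other probe sets were not above noise, at 500 on HuFL for APOC3 and 579 on subA and 0 on HuFL for F2. APOA1 lay at percentile 1.71. Of the brain markers 4 of 18 were above noise (22.2%, 6.41 to 47.6). GFAP read 1671 on HuFL but 46, not above noise, on subC, and TH and SYT1 were not above noise. Of the pancreas markers none of 10 was above noise, including CPB1 at 712, SST at 396 and CTRB1 at -300. These shares compare with random means of 11.7%, 14.2%, 15.0% and 10.8%. Without subB the liver share was 8.70% and the brain share 11.1% (random means 13.5% and 13.2%). On HuFL alone they were 0% and 6.25% (random means 7.24% and 7.13%). The insulin list's 21.6% lay within the intervals of all 4 of these lists.

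Stress response genes were above noise somewhat more often than random genes, and inflammatory genes were not. Of the immediate early and stress response genes 8 of 29 were above noise (27.6%, 12.7 to 47.2; random mean 12.6%), at the 98.3rd percentile of random lists, with HSPB1 above noise on 2 of 3 probe sets and MT2A, a metallothionein, at 6653, while FOSL1 read -1086. Of the cytokine and acute inflammation genes 1 of 25 was (4%, 0.101 to 20.4; random mean 12.1%), NFKBIA, an inhibitor of NF-kappaB, at 1244 against a noise level of 1230, while the chemokine CCL5 read 444 on subA and 190 on subC and IL4 at most -251 on HuFL. The median percentile of the stress genes lay at percentile 82.6 of random lists and their share at or above the 75th percentile at 70.6, or at 97.2 by the highest probe set of each gene. Without suffixed probe sets the stress share above noise was 8%, at percentile 47.6 of random lists.

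Control probe sets printed on all 5 arrays gave the spread between hybridisations, which by the labels used the same pool. GAPDH, read by its 3′ control probe set, was 14102 ± 8493 (SD, n = 5), and beta-actin, read likewise, 2554 ± 1351. The CreX spike, a phage transcript added to monitor hybridisation, was 9391 ± 3918 at its 3′ probe set. Over the 10 Affymetrix control probe sets above noise on every array, those for the opposite strand left out, the coefficient of variation had a median of 44.7% and ran from 38.8% to 60.2%. Leaving out subB, on which GAPDH read 4155, beta-actin 1173 and CreX 3663, brought the median to 27.9%, and dividing each array by its CreX mean brought it to 26.9%. The low place of subB held for values as deposited; divided by each array's trimmed mean, GAPDH on subB was 123 against 58.1 on subA and 73.5 on HuFL. Of 6 yeast probe sets on the 4 Hu35K arrays, none of the 24 values stood above noise.

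The ratio of 3′ to 5′ signal, a usual check of RNA and cDNA integrity, was 0.783 ± 0.129 (SD, n = 5) for GAPDH and 0.356 ± 0.106 for beta-actin. GAPDH ratios were 0.684, 0.732, 1.01, 0.764 and 0.728 on subA, subB, subC, subD and HuFL. Beta-actin ratios were 0.369, 0.359, 0.215, 0.511 and 0.328 in the same order. Beta-actin thus read lower at its 3′ than at its 5′ probe set on every array, so its ratio may reflect the probes rather than integrity. On subC the GAPDH 3′ probe set read 27517 and that of beta-actin 1014, the highest and the lowest of the 5 arrays, as they were after each of the 3 scalings tried.

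**Figure D3:**
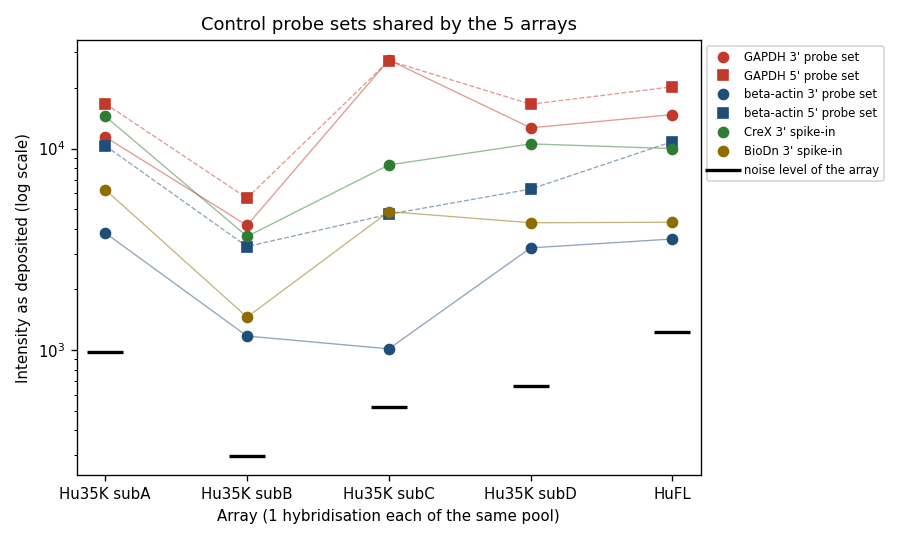
Deposited intensity (log axis) of control probe sets for GAPDH, beta-actin and the CreX and BioDn spikes on each of the 5 arrays, 1 hybridisation each, with the noise level of each array as a black bar; lines join the values of 1 probe set. As deposited, all 6 probe sets lie lower on subB than on subA, subD and HuFL, and on subC GAPDH reaches 27517 while the beta-actin 3′ probe set falls to 1014.

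A gene's percentile on HuFL told little of its percentile on the Hu35K arrays, which differ from HuFL both in probe sets and in hybridisation. For 2854 genes with probe sets on both HuFL and Hu35K, the percentiles on the array types correlated across genes with a Spearman coefficient of 0.146 (95% bootstrap interval over genes 0.106 to 0.185), genes not being independent replicates. Of the 175 genes above noise on HuFL, 75 were also above noise on a Hu35K array (42.9%, 35.4 to 50.5), against 23.2 if the calls were independent. Of the 2679 not above noise on HuFL, 303 were above noise on Hu35K (11.3%, 10.1 to 12.6). In all, 85.9% of the genes fell on the same side of noise on both types, where independent calls would give 82.2%. Without suffixed probe sets the correlation was 0.0825. Among genes above noise on at least 1 array type it was -0.0226, but this selection leaves out genes below noise on both and so lowers the correlation by construction.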

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

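All tests of explanations in this part were chosen after the results were seen. Of 17 quantities compared across the 5 arrays, 2 had an array whose gap to its neighbour exceeded the critical ratio of 0.71 of the whole range, and chance alone gives about 1 in 20.

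HuFL listed 1056 probe sets at exactly 0, against 13 to 64 on the Hu35K arrays (gap ratio 0.951), while 104 further HuFL values lay within 5 of 0; among the genes listed only at 0 were ACTA1, MYL2, MYBPC1 and HBB, transcripts known to be abundant in muscle fibres or, for HBB, in blood. Dim signals set to 0 are argued against as the whole cause: of 329 genes listed only at 0 on HuFL, 16.1% were above noise on Hu35K, with a lower 95% bound of 12.3%, above the 7.49% of genes with a dim value that was not 0. With every non-zero HuFL value up to the noise level counted as dim, that share was 10.2% (8.94 to 11.5). Probe sets of the same ID on subA are too few to decide: 3 of 60 at 0 on HuFL were above noise there (5%, 1.04 to 13.9), against 0 of 63 dim ones (upper bound 5.69%) and 23 of 404 that were not 0 (5.69%). Their median on subA was 58 where HuFL gave 0, 51 for the dim ones and 97 where it was not 0, so dim transcripts among the zeros are not excluded. The 95% interval of that 16.1%, 12.3 to 20.5, includes the 12.6% of genes with no 0, so values that were missing or failed whatever the transcript level, and were written as 0, remain a candidate explanation. The zeros also followed the name of the probe set, with 43.6% of IDs whose accession starts with X, Y or Z at 0 and 6.12% of all others. No biological explanation was tested, since the design holds 1 pool.

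On subC the GAPDH ratio of 3′ to 5′ signal was 1.01 (gap ratio 0.753), and across the control probe sets the median log2 ratio of subC to the other arrays was 1.03 for GAPDH and -0.55 for beta-actin. A single scale factor for the array is argued against by the difference of 1.58 between these transcripts, where the other 4 arrays reached at most 0.58. Whether the RNA was degraded is not decided. The beta-actin 3′ to 5′ ratio was lowest on subC at 0.215 (next lowest 0.328), while that of GAPDH was highest there. Beta-actin read lower at 3′ than at 5′ on every array, so its ratio may not follow integrity. Saturation of GAPDH on the other arrays is argued against by the dim array subB. There GAPDH over CreX was 1.13, against 3.32 on subC (SD of the other 4 arrays 0.282). A ceiling of signal on subC itself was not tested. On subC the GAPDH 3′ and 5′ probe sets read 27517 and 27302, near the array's highest value of 28158, that of the Alu probe set. The Alu probe set was also highest on subC, against 11290, 3882, 12050 and 13268 on subA, subB, subD and HuFL. A different aliquot of RNA, a different labelling reaction or a difference in the printed probes stays open and was not tested, and no biological explanation was tested in a design of 1 pool.

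The probe set for the opposite strand of the 3′ part of beta-actin, which no comparison used, averaged 1437 and stood above noise on all 5 arrays (2113, 574, 950, 1701 and 1849 on subA, subB, subC, subD and HuFL).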

How the results depend on the processing

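All alternatives named below as added were chosen after the data were seen. Signal over noise limits these results: only 5.04% to 7.98% of probe sets per array stood above noise. No paired analysis was possible because a single pool was hybridised once to each array design. Of the alternative values for the main lists, arrays, controls and array types, 137 stayed within the interval or SD of the reported value, 45 moved beyond it and 1 changed sign; for the other lists and groups 245 stayed and 45 moved. In both measures and every alternative, fast fibre, oxidative phosphorylation and ribosomal genes lay at the 100th percentile of random lists, slow fibre genes at or above 99.3, common sarcomere genes 99.8 and glycolysis 99.9. The cause of the shifts was not tested, except that a higher or lower threshold by construction calls fewer or more probe sets.

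Per array, in the order subA, subB, subC, subD and HuFL, the percentage above noise was 2.70, 1.55, 1.36, 2.77 and 3.18 with the 99th percentile, 71.3, 61.2, 59.9, 64.9 and 55.2 for any value above 0, and 26.3, 19.98, 22.2, 24.9 and 19.9 with the added 75th percentile. Without suffixed probe sets it was 6.65, 4.57, 3.95 and 5.22 on the Hu35K arrays, and 8.13 on HuFL without its values at 0 (added). With the 99th percentile the shares above noise were 48.3% for the common sarcomere, 68.1% for oxidative phosphorylation, 16% for the tricarboxylic acid cycle and 3.92% for insulin signalling; with the 75th they were 94.4% for oxidative phosphorylation, 64% for the tricarboxylic acid cycle, 60% for fatty acids and 52.9% for insulin signalling. Requiring as many probe sets above noise as not gave 5.88% for insulin signalling, and leaving out suffixed probe sets gave 34.6% for glycolysis and 15.4% for fatty acids. HuFL alone gave 45% for the common sarcomere, 35.7% for glycolysis and 4.88% for insulin signalling. For the share at or above the 75th percentile, the highest probe set of each gene gave 94.4% for oxidative phosphorylation, 70% for fatty acids and 58.8% for insulin signalling, HuFL alone 55% for the common sarcomere, and the Hu35K arrays alone 100% for fast fibres.

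The coefficient of variation of controls was 34.3% after scaling to the 75th percentile, 26.9% after scaling to CreX (added), and 27.9% to 50.6% with 1 array left out, the lowest without subB. Leaving out 1 array gave 3′ to 5′ ratios of 0.727 to 0.808 for GAPDH and 0.318 to 0.392 for beta-actin. Among genes above noise on at least 1 array type the correlation between types was -0.0226 and 15.7% lay on the same side of noise, both set by the selection, which leaves out genes below noise on both; without suffixed probe sets these were 0.0825 and 88.8%. Omission of subB or subC (added) moved no share of the main lists beyond its interval.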

Other observations

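All tests in this part, and the gene groups it describes, were chosen after the results were seen.

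Genes read above noise by every probe set, with at least 2 probe sets on different arrays, numbered 72 of 6921 eligible, against 18.6 if calls were independent. Of these, 27 stood in the lists, such as MYOZ1, TNNT1, MYL1, TNNI2, KLHL41 and PYGM, and 45 stood outside them. The latter included ADSS1 and AMPD1, the muscle forms of adenylosuccinate synthase and AMP deaminase in the purine nucleotide cycle, at 8955 on subD and 4277 on HuFL. TXNIP read 13793 on subD and 11328 on HuFL, and FTL, ferritin light chain, 8365 on HuFL and 4732 on subD. G0S2, an inhibitor of fat droplet lipolysis, read 4802 on HuFL and 1830 on subC. UNC45B, a myosin chaperone, read 1210 on subD but 303 on subB, just above that array's noise level of 299. The adiponectin receptor ADIPOR1 stood above noise on subA, subB and subD at 1057, 391 and 877. These genes were picked from the 45. Others among the 45 were GRM2 (389 on subB and 818 on subD), MAD2L2, at 304 on subB, and MXD3, at 672 on subD against a noise level of 667. Myoglobin (MB), with a single probe set, read 17699 on HuFL.

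Of the small heat shock proteins, which protect unfolding proteins, 7 of 9 measured members stood above noise with at least 1 probe set (77.8%, exact 95% interval 40.0 to 97.2). The mean of matched random lists was 12.8%. CRYAB read 11685 and HSPB2 1409 on HuFL, HSPB7 3903 and HSPB8 566 on subB, and HSPB6 stood above noise with 3 of 4 probe sets. HSPB3 at 143 and ODF1 at 1039 did not. The other probe sets of HSPB2, at 89 on subC, and of HSPB7, at 428 on subD, were not above noise. CRYAA was counted through 1 suffixed probe set, at 788 on subD against a noise level of 667, and was listed at 0 on HuFL. Of the enzymes of the purine nucleotide cycle and of phosphate transfer between nucleotides and creatine, 5 of 9 stood above noise (55.6%, 21.2 to 86.3), among them CKMT2, the mitochondrial creatine kinase of muscle, at 2654, while CKM, the cytosolic muscle form, was listed at 0 on HuFL. Since both groups were picked because members were bright, their counts describe the members and are no evidence for the group.

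On subB, values as deposited were dim: its 10 bright control probe sets had a median log2 ratio of -1.53 to their mean on the other arrays, or 0.346 of it, and its trimmed mean of 33.8 was the lowest of the arrays. Less labelled muscle RNA with spikes at their usual level is argued against, because the highest ratio of the 3 bright spike probe sets, those of CreX and BioDn, was -1.53. A dimmer spike probe set, that of BioC at 5′, was not above noise on every array. It fell less, to 479 on subB against 906, 667, 808 and 1170 on subA, subC, subD and HuFL. A single lower scale factor for the whole array, as from staining, scanning or the unstated scaling, remains a candidate explanation: the SD of the ratios on subB was 0.254, below the 0.327 to 0.844 of the other arrays fitted without it. Fitted with subB, as the like comparison, the SD was 0.268 on HuFL and 0.289 on subD, close to that of subB, and 0.478 on subA and 0.851 on subC. No biological explanation was tested, since all arrays carried the same pool.

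HuFL and subA share 464 probe set IDs, whose intensities correlated across probe sets with a Spearman coefficient of 0.269, or 0.286 without HuFL values at 0. Of the 17 above noise on HuFL, 4 were above noise on subA (23.5%, exact 95% interval 6.81 to 49.9), against 0.953 if calls were independent, and those 4 differed by 0.48 ± 0.34 (SD, n = 4) in log2 of subA over HuFL. Whether a shared ID stands for identical probes on both designs is not given in the sources used here.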
